A study of Homo sapiens with 6 samples.

How the data were processed

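Gene expression was measured by RNA sequencing in 6 libraries of A549, a human lung adenocarcinoma cell line. Of these, 3 libraries came from cells that received a negative-control siRNA and 3 from cells that received an siRNA against HNRNPD. HNRNPD encodes AUF1, an RNA-binding protein known to bind AU-rich sequences in the 3' untranslated regions of mRNAs. Per the labels, RNA was extracted with Trizol, libraries were made with the Illumina TruSeq RNA kit from 1 ug of total RNA, and sequencing was done on a HiSeq instrument. The labels number the libraries of each group 1 to 3. They do not say whether the 3 libraries with HNRNPD siRNA received the same siRNA sequence or different ones, nor that they came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

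The values used are whole-number read counts per gene in 1 deposited table, and they sum to a different total in each library. Per the submitters' processing notes, Bowtie 0.12.2 was used and the builds GRCh38 and mm8 are named, with no role given for either. Gene coordinates are as the deposited table gives them and were matched to a GRCh38 annotation. The counting program, the annotation version and the strand setting are not given in the sources used here. The table also gives each gene's length in bases, which was used only to look for a length trend. It holds 56303 rows, of which 17872 have no count in any library. A spreadsheet had turned 28 gene names into dates, and 26 of them were recovered from their coordinates. Gene types and older or newer symbols were taken from GENCODE 29, which matched 35425 rows by name and overlapping position and 19896 by position alone, while 982 stayed unmatched.

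Some properties of the counts limit what can be read from them. Among counts of 1 to 20, between 66.2% and 69.5% per library were even, against 50.6% to 51.7% of counts over 200, as when both mates of a read pair are counted, so a count may stand for less than 1 fragment. In 181 genes that lie within the exons of a well-covered gene on the opposite strand, the median density of counts was 0.441 of the partner's, and 84.5% of them had at least 0.1 of it. With no strand setting given, counts over bases that a gene shares with an antisense gene are not assigned to either with certainty here. Exonic bases are shared with another gene in 15650 rows, and counts of such genes may hold reads of their neighbours. Among the genes named, the fraction of exonic bases shared was 0.484 for IFNAR2, 0.452 for SP110, 0.332 for MTHFD2, 0.311 for PLAU, 0.304 for XPC, 0.301 for ACTA2, 0.256 for RPS2, 0.239 for HSPE1, 0.233 for MALAT1, 0.22 for DIABLO and 0.212 for PSMB8. It was between 0.101 and 0.18 for ALDOC, CCND1, THY1, IL10RB, HMGCS1, KRT18, RPL38 and HLA-B. Those of XAF1, IFNA1, IRF9, SRXN1, CD68, AC009950.1 and HSPE1-MOB4 are given with their values, and several more named genes share smaller fractions. Read pairs were not separated by molecular identifiers, so limits from counts cover counting error only.

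The totals were 42697412, 42607632 and 43005090 counts in the control libraries and 37151094, 40462117 and 39941137 in the HNRNPD siRNA libraries. A count of 0 allows up to 3 counts, which is 0.0698 to 0.0808 counts per 1000000 counts (CPM). Where both mates of a pair are counted, 3 fragments give more than 3 counts, so this limit may be too low. No pair of replicates was close enough to be 1 library deposited more than once, as chi-square per degree of freedom ran from 6.63 to 27.67 between replicates.

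The groups were compared with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust estimation on the counts as deposited, TMM normalization, the filter filterByExpr and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 20465 genes that passed the filter, and a gene is called higher or lower at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the size of the log2 fold change and its F statistic. CPM values use the TMM-scaled totals, and errors of group means are SDs over 3 libraries. Fold sizes are those of the fitted model.

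Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, for the 21 of 22 lists that had at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Adjusted p-values of lists are over these 21 lists. The counts of called members adjusted over the list alone equalled those adjusted over all genes in 18 of the 22 lists, and the exceptions are given with each list. The 22 lists, the design and the rule for naming genes were fixed before the data were examined. The rule takes HNRNPD, the 8 genes with the largest rise and the 8 with the largest fall (protein coding, a mean of at least 5 CPM, no overlap between the groups), the 5 genes per direction with the smallest p, the 4 members of each list with the smallest p together with members that are exceptions, and the 2 called genes per direction with the highest mean CPM. Outside the rule, 19 genes were chosen after their values were seen, namely ALDOC, LDHA, SLC2A1, GPX4, CCL5 and LAMP3 from the lists and the others from the lists added later. PTPRC and the interferon genes, which are given as counts, were singled out then as well. Some genes that the rule takes are not reported here. A further 3 lists, of interferon genes, of interferon receptors and RNA sensors, and of class I antigen presentation, were chosen after seeing the data.

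The test was tried on simulated counts for this comparison, with 200 of the 56303 genes changed. At 1.25-fold, 19 of 50 changed genes were recovered, at 1.5-fold 44 of 50, at 2-fold 49 of 50 and at 4-fold 50 of 50, with 15 of the unchanged genes called among 19902 tested. Camera called both changed lists among 20 simulated ones and 0 of the unchanged ones. The changed genes had a control mean of at least 5 CPM, and all genes were drawn independently. In the data 56.1% of tested genes were called, and the estimated correlation reached 0.84 for interferon-stimulated genes. These rates therefore hold for the simulated setting and do not give the false calls of camera in the data. Alternatives that were tried are DESeq2 size factors, library totals only, no filter on low counts, at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each library in turn. The 3 alternatives added later, after seeing the data, were counts divided by 2, genes whose exons overlap no other gene, and the table without mitochondrial genes. Exon overlap was found with bedtools 2.31.1. Sequences of 3' untranslated regions came from GENCODE 29 and were analysed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.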

Results

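RNA-seq read counts were compared between A549 cells with a negative-control siRNA (3 libraries) and A549 cells with an siRNA against HNRNPD (3 libraries). A549 is an established line of human lung adenocarcinoma. The libraries held 37151094 to 43005090 counts, and 28703 to 30481 genes had at least 1 count in each. The share of counts on the mitochondrial chromosome was 15.72%, 16.09% and 18.5% in the control libraries and 18.05%, 15.1% and 15.21% in the HNRNPD siRNA libraries. The first principal component took 77.3% of the variance and separated the groups, while the second took 6.8% and set the HNRNPD siRNA libraries apart from each other, with replicate 3 at the far end from replicate 1.

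HNRNPD mRNA fell from 950.1 ± 13.2 CPM (SD, n = 3) in the control libraries to 169 ± 7.29 CPM (SD, n = 3) in the HNRNPD siRNA libraries. The fold change was 5.62, at a log2 fold change of -2.49 (SE 0.06, edgeR adjusted p = 1.38e-15). The gene lies on chromosome 4 from 82352498 to 82374503 (GRCh38, minus strand). Its levels were 965.4, 942.8 and 942.2 CPM in control replicates 1 to 3 and 177, 162.7 and 167.5 CPM in HNRNPD siRNA replicates 1 to 3, which matches the labels in all 6 libraries. HNRNPDL, a paralog of HNRNPD, rose 1.89-fold, from 226 to 427 CPM (log2 fold change 0.92, SE 0.06, adjusted p = 2.75e-10).

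**Figure D1:**
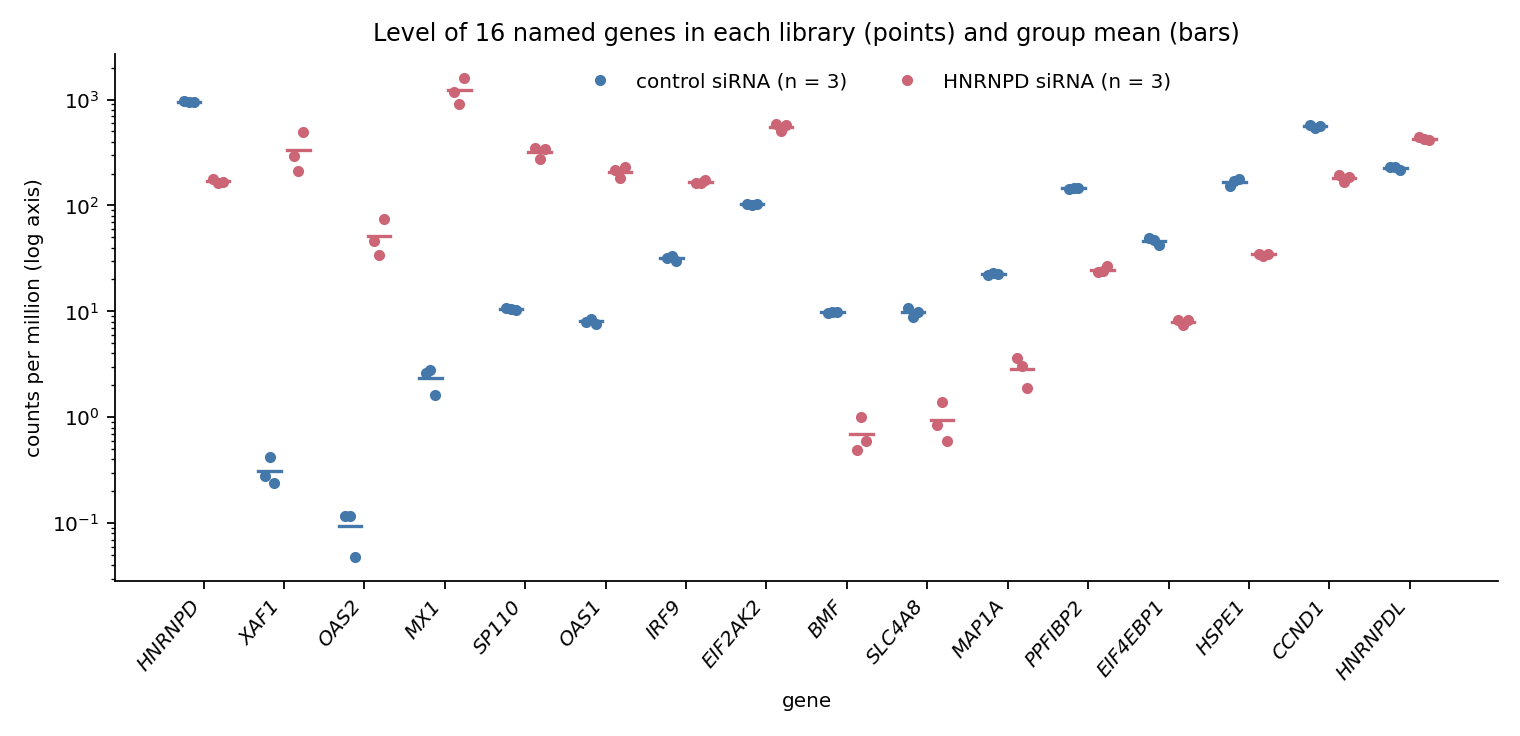
CPM (log axis) of 16 named genes in each library. Points are the 3 control libraries (blue) and the 3 HNRNPD siRNA libraries (red), and bars are group means. HNRNPD falls from a mean of 950.1 to 169 CPM, and MX1 rises from 2.35 to 1220.5 CPM.

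The comparison of all genes asks which mRNAs differ once HNRNPD is lowered. Of 20465 tested genes, 5803 were higher and 5687 were lower after HNRNPD siRNA, which together is 56.1% of those tested. A change of at least 2-fold was found for 2079 of the higher and 1247 of the lower genes. Among 14326 protein-coding genes, 4204 were higher and 4771 lower, with 1236 and 918 changed at least 2-fold. The median log2 fold change of all tested genes was 0.01, where the scaling sets it near 0, and the biological coefficient of variation was 8.3%. Because replicates were this close, folds as small as 1.10 were called among genes with a mean of at least 5 CPM. Of the called genes, 5937 (51.7%) share exonic bases with another gene, as do 10683 of the 20465 tested. Of 2265 antisense genes tested, 587 were called higher and 373 lower, and part of their counts may come from genes on the opposite strand. With at least 1 CPM required in 3 libraries, 1356 genes were at least 2-fold higher and 828 at least 2-fold lower. Among genes whose exons overlap no other gene, 2745 were higher and 2819 lower, of 9782 tested.

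**Figure D2:**
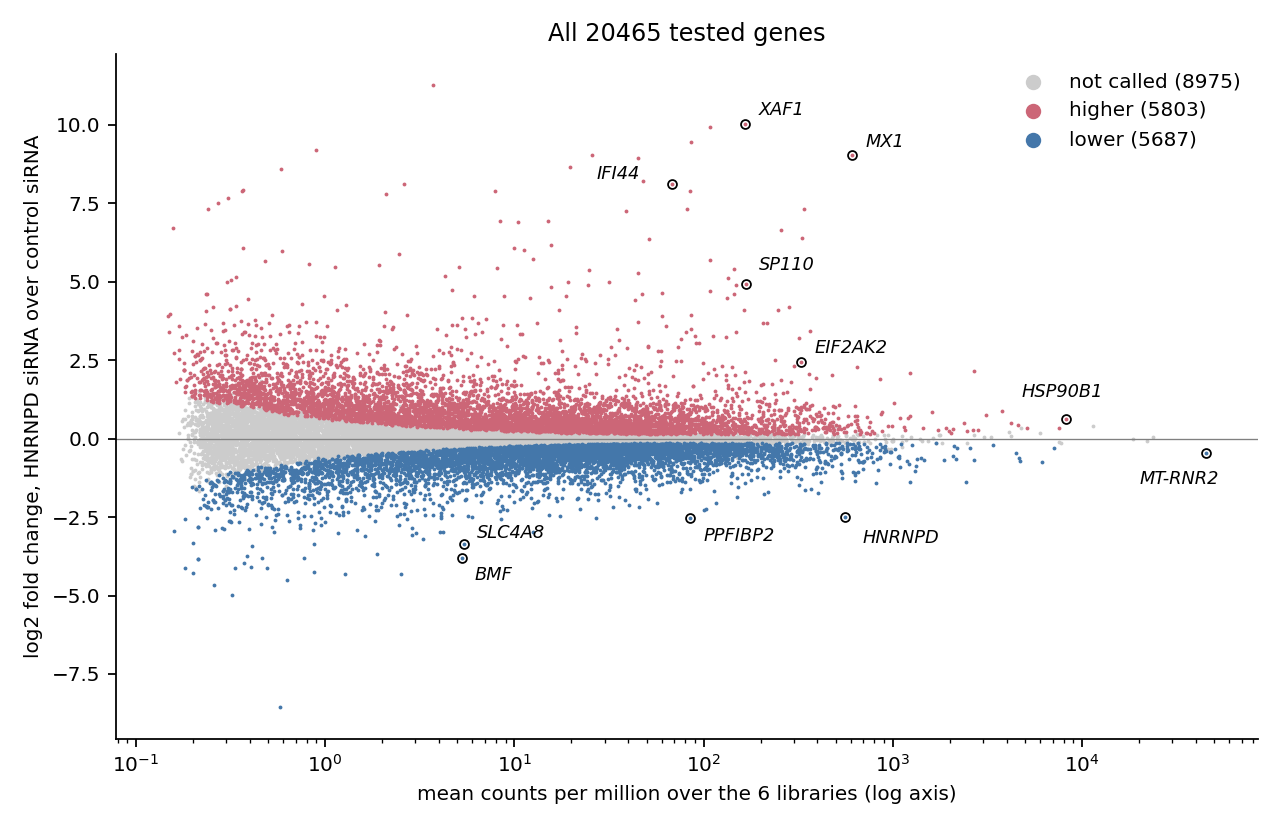
Log2 fold change of HNRNPD siRNA over control siRNA against mean CPM over the 6 libraries (log axis) for all 20465 tested genes. Red points are the 5803 genes called higher, blue points the 5687 called lower and grey points the 8975 not called, with some named genes circled.

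Among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, the 8 largest rises were all of genes known to be induced by interferon. XAF1, a pro-apoptotic partner of XIAP, rose from 0.31 ± 0.09 to 332 ± 144 CPM (SD, n = 3), a fitted 1046-fold change (log2 fold change 10.03, SE 0.64). OAS2, a sensor of double-stranded RNA that activates RNase L, had a log2 fold change of 9.04 (SE 0.67), and the antiviral GTPases MX1 and MX2 had 9.02 (SE 0.40) and 8.66 (SE 0.66). RSAD2, which encodes viperin, had 8.94 (SE 0.81), OASL 8.19 (SE 0.61), IFI44 8.12 (SE 0.36) and IFI44L 7.87 (SE 0.42). Their adjusted p-values ran from 2.84e-05 for IFI44 to 0.000832 for RSAD2. Without control replicate 1 the log2 fold change of RSAD2 was 9.53. XAF1 shares a fraction of 0.383 of its exonic bases with a neighbouring gene. The smallest p-values among rises belonged to AC009950.1, SP110, OAS1, IRF9 and EIF2AK2, with adjusted p-values of 1.38e-15 for AC009950.1 and SP110, 2.73e-15 for OAS1 and IRF9 and 4.09e-15 for EIF2AK2. AC009950.1 lies wholly inside exons of SP110, a nuclear body protein gene, so the counts of these genes are not separate measurements. IRF9, a subunit of the transcription factor ISGF3, rose 5.25-fold and shares a fraction of 0.484 of its exonic bases with a neighbouring gene. EIF2AK2, which encodes the RNA-activated kinase PKR, rose 5.42-fold from 103 to 556 CPM.

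All 32 tested interferon-stimulated genes were higher, each by at least 2-fold, with a median log2 fold change of 5.68 and a range of 1.69 to 10.03 (camera adjusted p = 7.62e-22). With an estimated correlation the list was not called (adjusted p = 0.28). The components of the interferon-activated transcription complex rose, with STAT2 9.41-fold higher and IRF9 as given above, as did the transcription factor IRF7 (23.5-fold) and OAS1 (26.0-fold). The median level of the 32 genes was 4.01, 4.03 and 3.66 CPM in control replicates 1 to 3, and 147.86, 111.38 and 173.28 CPM in HNRNPD siRNA replicates 1 to 3. Of the 32 genes, 31 had their highest level in HNRNPD siRNA replicate 3. HNRNPD itself differed by 1.09-fold between the highest and the lowest of the HNRNPD siRNA libraries, against 1.56-fold for the median of the interferon-stimulated genes. Without HNRNPD siRNA replicate 3 the genes called numbered 5718 higher and 5826 lower.

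Among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, the largest falls were of BMF, SLC4A8, MAP1A, CYP4F12, PPFIBP2, EIF4EBP1, CA8 and HNRNPD. BMF, a pro-apoptotic BH3-only gene, fell from 9.82 to 0.70 CPM (log2 fold change -3.79, SE 0.18, adjusted p = 6.67e-12). SLC4A8, a sodium-driven bicarbonate exchanger, had a log2 fold change of -3.37 (SE 0.20) and MAP1A, a microtubule-associated protein, of -2.98 (SE 0.15). CYP4F12, a cytochrome P450, had -2.57 (SE 0.12), PPFIBP2, which encodes liprin beta 2, -2.54 (SE 0.06), EIF4EBP1, a repressor of cap-dependent translation, -2.52 (SE 0.08), and CA8, a carbonic anhydrase-related protein, fell 5.68-fold (SE of the log2 value 0.15). Among the smallest p-values of falls were also HSPE1, the mitochondrial co-chaperonin, with a 4.81-fold fall from 166 to 34.5 CPM, and the read-through gene HSPE1-MOB4, whose exons lie wholly within other genes. Among the most abundant genes, the mitochondrial 16S ribosomal RNA MT-RNR2 fell from 52612 to 38301 CPM (log2 fold change -0.46, SE 0.09) and the nucleolar protein NCL from 7799 to 6355 CPM (-0.30, SE 0.07). The endoplasmic reticulum chaperone HSP90B1 rose from 6531 to 10007 CPM (0.62, SE 0.06). The nuclear long non-coding RNA MALAT1, at 6736 and 8455 CPM, was called at an adjusted p of 0.0465, and 8 of its 15 alternatives ended the call, 4 of them by leaving out 1 library (control replicate 1 or 3, or HNRNPD siRNA replicate 2 or 3), with an adjusted p of up to 0.34.

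Genes of hypoxia and glycolysis were mostly lower, with 25 of 34 lower and 5 higher, and a median log2 fold change of -0.84 (camera adjusted p = 3.01e-08, and adjusted p = 0.15 with an estimated correlation). BNIP3L, a mitophagy receptor, fell 4.31-fold, PFKFB3, which makes the activator of phosphofructokinase, 2.69-fold, and the membrane carbonic anhydrase CA12 2.35-fold. Aldolase C (ALDOC) fell 7.84-fold, lactate dehydrogenase A (LDHA) 2.40-fold and the glucose transporter SLC2A1 2.87-fold. The 5 exceptions were another glucose transporter, SLC2A3, which rose 3.03-fold (adjusted p = 1.39e-13), and P4HA2, ADM, HK2 and PFKL, at log2 fold changes of 0.73, 0.52, 0.78 and 0.24. The call of HK2 was lost without control replicate 1 (adjusted p = 0.0525) and that of PFKL without control replicate 3 (adjusted p = 0.0534).

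In the list of NRF2, glutathione and ferroptosis genes, 28 of 31 were lower and 2 higher, and the median log2 fold change was -0.89 (camera adjusted p = 1.09e-13, and adjusted p = 0.28 with an estimated correlation). The subunits of glutamate-cysteine ligase, which makes the precursor of glutathione, both fell, GCLC by 2.57-fold and GCLM by 2.51-fold. The glutathione peroxidases GPX2 and GPX4 had log2 fold changes of -1.90 and -1.32. Sulfiredoxin (SRXN1) fell 2.19-fold and shares a fraction of 0.85 of its exonic bases with another gene. The exceptions were TFRC and ME1, at log2 fold changes of 0.25 and 0.21. The call of ME1 was lost without control replicate 2 (adjusted p = 0.16) or 3 (0.0871), or without HNRNPD siRNA replicate 1 (0.11) or 2 (0.14).

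Cytosolic ribosomal protein genes were lower in 45 of 49 cases and higher in 1, RPL11. Their median log2 fold change was -0.44, with quartiles of -0.56 and -0.36 (camera adjusted p = 6.98e-12, and adjusted p = 0.40 with an estimated correlation). RPL6 fell 2.22-fold, RPS24 1.73-fold, RPS2 1.53-fold and RPL38 1.44-fold. Ribosomal protein genes have many processed copies in the genome, and how reads matching several places were counted is not given in the sources used here.

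Of 35 genes of G2/M and mitosis, 29 were lower and 2 higher, or 31 lower when adjusted over the list alone, with a median log2 fold change of -0.44 (camera adjusted p = 3.48e-07, and adjusted p = 0.40 with an estimated correlation). The kinase NEK2 fell 1.64-fold, the proliferation marker MKI67 1.54-fold and cyclin B2 (CCNB2) 1.81-fold, while CENPF, a kinetochore protein, rose 1.62-fold. The other exception, the checkpoint kinase gene BUB1, was not called without control replicate 1 (adjusted p = 0.0527) or 3 (adjusted p = 0.0697). Of 37 genes of DNA replication and G1/S, 23 were lower and 4 higher, with a median of -0.25 (camera adjusted p = 0.000108, and adjusted p = 0.37 with an estimated correlation). UHRF1 fell 2.53-fold, TK1 2.64-fold and the helicase subunits MCM2 and MCM5 2.11-fold and 1.84-fold. PCNA, the sliding clamp, was 1.59-fold higher. Genes of homologous recombination and the Fanconi anaemia pathway went both ways, with 8 higher and 11 lower of 31 (camera adjusted p = 0.46). RAD50 and BRCA2 rose 1.57-fold and 2.14-fold, and FANCI fell 1.46-fold.

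Of 29 p53 target genes, 16 were higher and 5 lower, or 17 higher when adjusted over the list alone, and the median log2 fold change was 0.34 (camera adjusted p = 0.0034, and adjusted p = 0.18 with an estimated correlation). XPC, a DNA damage sensor, rose 2.82-fold, BTG2 3.19-fold, FDXR 2.12-fold and MDM2 1.86-fold. CDKN1A, the p21 gene, had a log2 fold change of -0.17 and was not called, but it was without control replicate 2 (adjusted p = 0.0368) or HNRNPD siRNA replicate 3 (adjusted p = 0.0423). Apoptosis and survival genes were not called as a list (camera adjusted p = 0.23), with 13 higher and 6 lower of 30. The initiator caspase CASP8 rose 2.36-fold, while BMF fell as given above and DIABLO fell 1.60-fold. Of the 16 replication-dependent histone genes that could be tested, 11 were higher and 0 lower (edgeR), with a median log2 fold change of 1.24 (camera adjusted p = 0.00176, and adjusted p = 0.15 with an estimated correlation). They were of low level, as with HIST1H2AC at 3.71 and 10.04 CPM, HIST1H2BD at 0.77 and 3.23 CPM, HIST1H1C at 5.06 and 11.9 CPM and HIST2H4A at 2.58 and 6.15 CPM. These are counts of whatever histone RNA the TruSeq RNA libraries captured. A rise in the histone mRNA of replicating cells cannot be read from them.

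Cholesterol and fatty acid synthesis genes were lower in 22 of 32 cases and higher in 5, with a median of -0.33 (camera adjusted p = 0.000126, and adjusted p = 0.15 with an estimated correlation). The desaturase SCD fell 2.05-fold, HMGCS1 1.92-fold and ACLY 1.88-fold. In the list of ATF4 and unfolded protein response genes, 11 were higher and 13 lower of 29 (camera adjusted p = 0.37). The serine and one-carbon synthesis genes PHGDH, PSAT1 and MTHFD2 fell 2.15-fold, 2.01-fold and 2.24-fold. The endoplasmic reticulum chaperones CALR and HSP90B1 rose 1.63-fold and 1.53-fold.

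**Figure D3:**
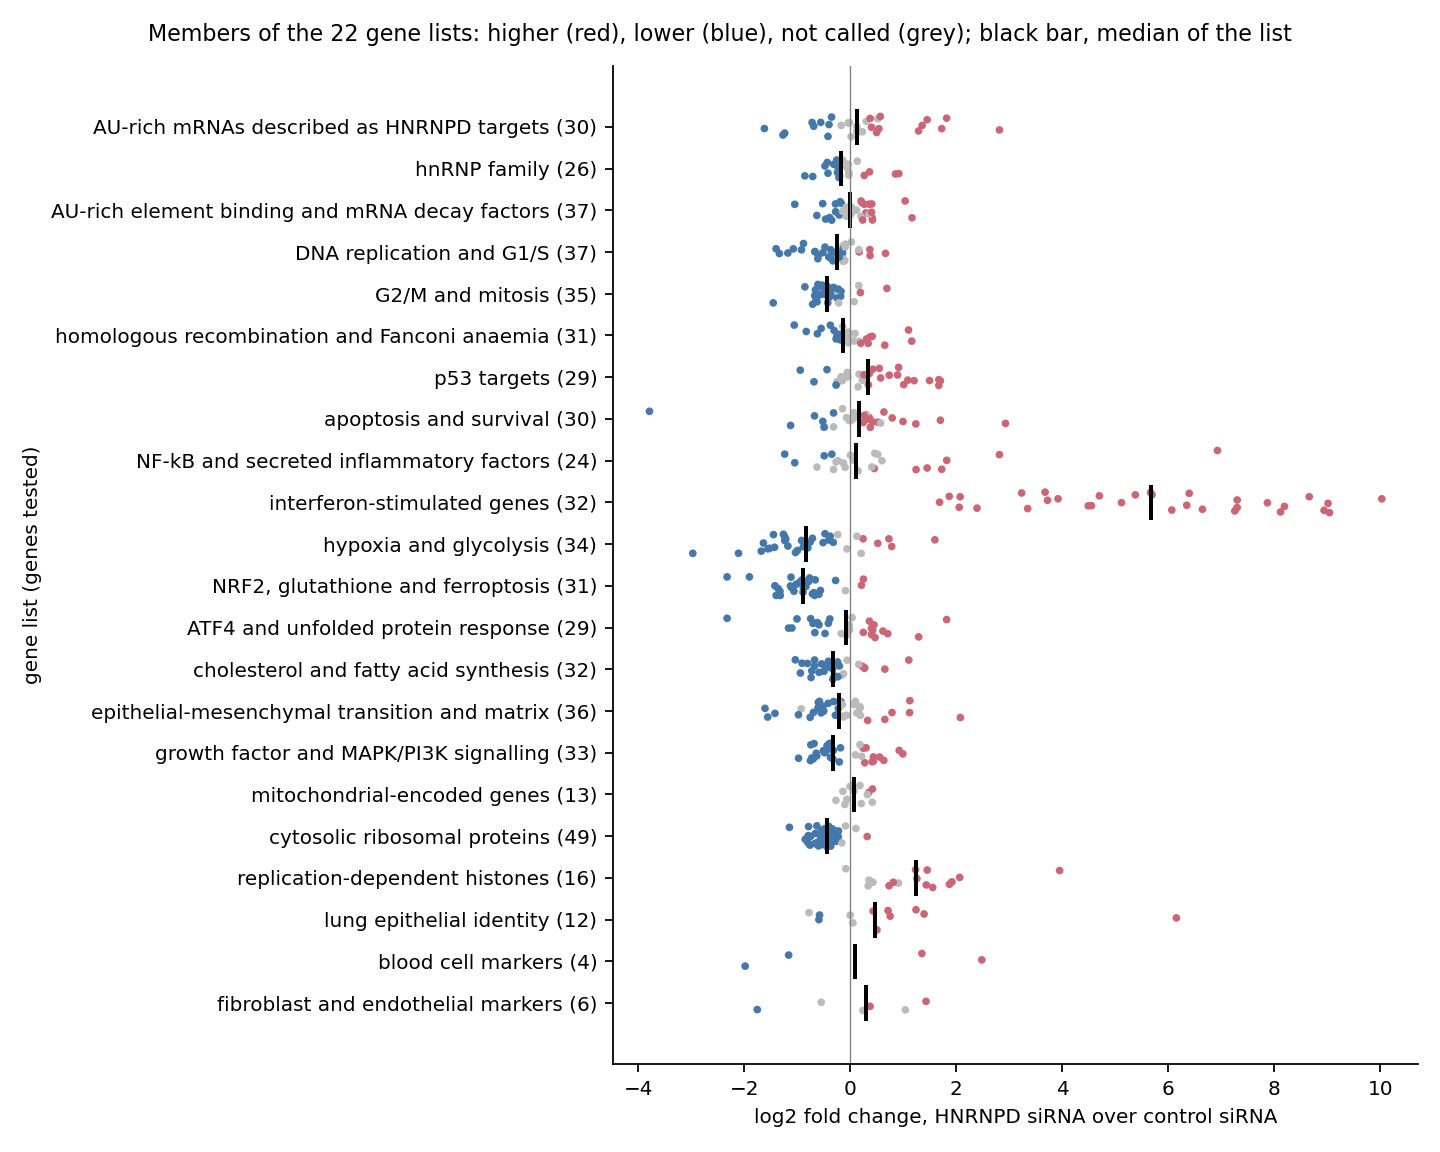
Log2 fold change of HNRNPD siRNA over control siRNA for the tested members of the 22 gene lists, with the number tested in brackets. Red points were called higher, blue points lower and grey points neither, and black bars are medians, from 5.68 for interferon-stimulated genes to -0.89 for NRF2, glutathione and ferroptosis genes.

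Genes tied to the known functions of HNRNPD moved in both directions. Of 30 AU-rich mRNAs described as its targets, 11 were higher and 9 lower, with a median log2 fold change of 0.14 (camera adjusted p = 0.76). The median was 0.04 without HNRNPD siRNA replicate 3 and 0.22 without replicate 1. Cyclin D1 (CCND1) fell 3.07-fold and the urokinase gene PLAU 2.41-fold, whereas the chemokine gene CXCL1 rose 2.74-fold and PTGS2, which encodes cyclooxygenase 2, 3.31-fold. In the hnRNP family, without HNRNPD itself, 4 were higher and 13 lower of 26, with a median of -0.17 (camera adjusted p = 0.0505, and adjusted p = 0.57 with an estimated correlation). This list was called under 7 of 15 alternatives, namely no filter on low counts (adjusted p = 8.83e-05), DESeq2 size factors (0.0474), fry (0.0343), the table without mitochondrial genes (0.0461), and without control replicate 2 (0.0353) or HNRNPD siRNA replicate 1 (0.015) or 3 (0.0425). HNRNPUL1 fell 1.81-fold and HNRNPR 1.63-fold, while HNRNPM rose 1.81-fold and HNRNPDL rose as given above. Of 37 factors that bind AU-rich elements or degrade mRNA, 12 were higher and 11 lower (camera adjusted p = 0.78). Their median of -0.01 and mean of 0.02 differ in sign, and the median ran from -0.05 to 0.02 over the alternatives, being above 0 with library totals only, with at least 1 CPM in 3 libraries and with counts divided by 2. TNRC6A fell 2.07-fold and CNOT6 1.55-fold, and the nucleases PAN2 and XRN1 rose 2.24-fold and 2.05-fold.

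Signalling and inflammatory genes were mixed. Of 24 NF-kB and secreted inflammatory factors, 7 were higher and 4 lower (camera adjusted p = 0.46), with CXCL1 and PTGS2 as given above, TRAF1 2.37-fold and IL11 3.53-fold higher. CCL5, a chemokine that is also inducible by interferon, had the largest rise of this list, from 0.13 to 16.6 CPM (edgeR), and was not called by limma-voom (adjusted p = 0.0633). Its levels in HNRNPD siRNA replicates 1 to 3 were 11.4, 9.57 and 28.9 CPM, and without replicate 3 its log2 fold change was 6.26 against 6.93 with all libraries. The median log2 fold change of the list was 0.10, and -0.08 without HNRNPD siRNA replicate 3, in a range of -0.08 to 0.25 over the libraries left out in turn. In growth factor and MAPK/PI3K signalling, 10 were higher and 19 lower of 33 (camera adjusted p = 0.21, with adjusted p = 0.0383 with no filter on low counts and 0.0062 by fry). The receptor genes FGFR1 and MET fell 1.97-fold and 1.61-fold, and RPTOR rose 1.90-fold. Of 36 genes of the epithelial-mesenchymal transition and matrix, 6 were higher and 17 lower, or 7 higher when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0357, and adjusted p = 0.21 with an estimated correlation). Those that fell included the epithelial genes ITGB4 (3.05-fold), KRT18 (1.69-fold) and KRT8 (1.62-fold), and those that rose included the matrix protease gene MMP14 (4.22-fold). This list was not called by camera without HNRNPD siRNA replicate 2 (adjusted p = 0.073), in a range of 0.0161 to 0.073 over the 6 libraries left out in turn. Nor was it called with at least 1 CPM required in 3 libraries (adjusted p = 0.0771) or with the replicate block (adjusted p = 0.0518).

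Of 13 protein-coding mitochondrial genes, 2 were higher (MT-CO2 and MT-ND3) and 0 lower in edgeR, with a median log2 fold change of 0.07 (camera adjusted p = 0.46). That median was -0.08 without HNRNPD siRNA replicate 1, and leaving out each library in turn gave a range of -0.08 to 0.26. Leaving out HNRNPD siRNA replicate 3 ended the call of MT-CO2 (adjusted p = 0.14) and of MT-ND3 (adjusted p = 0.11), and leaving out control replicate 1 that of MT-ND3 (adjusted p = 0.059). MT-ND4 and MT-ND4L were not called at log2 fold changes of 0.42 and 0.32. Both were called without HNRNPD siRNA replicate 2 (adjusted p = 0.0003 and 0.000163) and with library totals only (0.013 and 0.0446), and MT-ND4 also without control replicate 3 (0.0364). In lung epithelial identity, 7 were higher and 2 lower of 12 tested (camera adjusted p = 0.22). AGER rose 2.63-fold and the mucin gene MUC5B 2.36-fold, while CAV1 and FOXA2 had log2 fold changes of -0.59 and -0.58. LAMP3, a lamellar body gene that interferon also induces, rose from 0.43 to 31.0 CPM.

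Markers of other cell types gave no common direction. Only 4 of 15 blood cell markers passed the filter, too few for a list test. NKG7 and CD68 were higher, at 0.64 and 1.65 CPM and at 18.1 and 101 CPM, and CD14 and ITGAM lower, at 2.07 and 0.51 CPM and at 4.52 and 2.03 CPM. CD68 shares a fraction of 0.858 of its exonic bases with another gene. PTPRC, the pan-leukocyte CD45 gene, had 4 counts in the 3 control libraries and 0 in the 3 HNRNPD siRNA libraries. Of 6 fibroblast and endothelial markers tested, ACTA2 (2.69-fold) and COL1A1 (1.30-fold) were higher and THY1 lower, or 3 higher when adjusted over the list alone (camera adjusted p = 0.46). The calls of COL1A1 and THY1 were lost without control replicate 3 or HNRNPD siRNA replicate 1, and without control replicate 1 or HNRNPD siRNA replicate 1 or 2, with adjusted p-values of up to 0.11 and 0.17. Without HNRNPD siRNA replicate 3 the log2 fold change of THY1 was -3.11, against -1.75 with all libraries.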

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

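The alternatives were planned before the data were examined, except the counts divided by 2, the genes without exon overlap and the table without mitochondrial genes, which were chosen after seeing the data. HNRNPD was lower under all 15 alternatives that gave it a value, at log2 fold changes of -2.54 to -2.46. Under the 16 alternatives for single genes, counts stayed within 1.5 times those reported except in the cases that follow. With at least 1 CPM in 3 libraries, which tests fewer genes of low level, 1356 genes were at least 2-fold higher and 828 at least 2-fold lower. Among genes whose exons overlap no other gene, a smaller set, 2745 were higher and 2819 lower, with 1117 and 731 changed at least 2-fold. Leaving out each library in turn gave 5125 to 5718 higher, 5170 to 5826 lower, 1988 to 2139 at least 2-fold higher and 1212 to 1297 at least 2-fold lower. DESeq2 called 5056 genes higher and 5284 lower, and 10004 of the genes called by edgeR were also called by DESeq2, 0 of them in the opposite direction. No scaling moved the median of all genes by over 0.1 on the log2 scale. Each of these scalings compares shares of the counts in a library. A common rise or fall of mRNA per cell would therefore not show.

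Of the gene lists, 10 were called by camera, 0 with an estimated correlation and 17 by fry. The estimate was 0.01 for p53 targets, 0.0044 for cholesterol and fatty acid synthesis, -0.0045 for the epithelial-mesenchymal transition and -0.0206 for histones. As these lie at or below the preset 0.01, a high correlation among members does not account for those lost calls. For p53 targets, where both correlations were 0.01, the unadjusted camera p was 0.00146 with the preset and 0.0335 with the estimate. The form with an estimate thus gave a larger p at the same correlation. For such lists the lost call is not by itself evidence against them. The other called lists had estimates of 0.06 (hypoxia and glycolysis) to 0.84 (interferon-stimulated genes). The cause was not tested for these or for fry. The 7 lists that fry called and camera did not were the hnRNP family, homologous recombination and Fanconi anaemia, apoptosis, ATF4 and unfolded protein response, growth factor signalling, lung epithelial identity, and fibroblast and endothelial markers. Fry asks only whether members move one way on balance, and the lists it called had the direction that camera gave. Leaving out each library gave 9 to 11 lists. The numbers in the labels were not taken to pair the libraries, as same-numbered libraries had correlations of their deviations of 0.014 to 0.026, under the minimum of 0.1, although 5 of 6 libraries correlated best with their own number. With the replicate block, 5792 genes were higher, 5737 lower, 2052 at least 2-fold higher and 1251 at least 2-fold lower, HNRNPD had a log2 fold change of -2.49 and 9 lists were called. The block changed the call of the list of the epithelial-mesenchymal transition and matrix (adjusted p = 0.0518, in a range of 0.000541 to 0.21 over its alternatives) and of no other list or named gene. Of 139 genes taken by the rule or chosen later, 126 had the same call under every alternative that gave one, 13 did not and 0 reversed. These 13 were MALAT1, MT-CO2, MT-ND3, MT-ND4, MT-ND4L, COL1A1, THY1, PFKL, HK2, BUB1, ME1, CDKN1A and CCL5. Depth limits the genes of low level, as a count of 0 allows up to 0.0808 CPM in the shallowest library, or more where both mates are counted.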

Other observations

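The test of 1 siRNA seed behind most of the falls, made 1 heptamer at a time, and the test of blood cells, were chosen after the results they bear on were seen. The lists in the next paragraph were also chosen then.

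Of 5 interferon genes tested, 4 were higher in the HNRNPD siRNA libraries (camera p = 0.0102, and p = 0.24 with an estimated correlation). IFNL1, IFNL2 and IFNL3, which encode type III interferons, had 2, 2 and 0 counts over the 3 control libraries and 496, 618 and 884 counts over the 3 HNRNPD siRNA libraries. How reads matching several places were counted is not given, so counts of these related genes may not be separate measurements. The other called gene, IFNA1, had 15 counts in the control libraries and 40 in the HNRNPD siRNA libraries. It shares a fraction of 0.252 of its exonic bases with IFNA8. IFNB1 was too low to be tested, with 0 counts in each control library and 8, 22 and 46 counts in HNRNPD siRNA replicates 1 to 3. The RNA sensors DDX58 (RIG-I), IFIH1 (MDA5), DHX58 and TLR3 rose 22.5-fold, 34.8-fold, 43.4-fold and 14.4-fold, and ADAR, which edits double-stranded RNA, 2.83-fold. The receptor genes IFNAR1, IFNAR2 and IL10RB were 1.90-fold, 1.98-fold and 1.76-fold lower. Of the 17 receptors and sensors, 10 were higher and 5 lower (unadjusted camera p = 0.0189, and p = 0.40 with an estimated correlation). DDX58 and IFIH1 also belong to the fixed list of interferon-stimulated genes. This p is therefore not a separate test of the rise of that list. All 20 genes of class I antigen processing and presentation were higher (camera p = 2.39e-12, and p = 0.086 with an estimated correlation), with a median log2 fold change of 1.72. Among them NLRC5, the activator of class I transcription, had a log2 fold change of 4.65, and TAP1 rose 7.54-fold, PSMB8 6.43-fold, HLA-B 7.60-fold and B2M 3.27-fold.

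For the rise of interferon-stimulated genes, blood or immune cells in the siRNA cultures are argued against by PTPRC, which had a highest count of 0 in an siRNA library. Sensing of the transfected siRNA and not the loss of HNRNPD cannot be told apart from an effect of the loss, as 0 groups are labelled as a second HNRNPD siRNA of another sequence. The control cells also received an siRNA, so transfection alone does not separate the groups, but a sequence or preparation that is sensed more strongly may. That the interferon-stimulated genes were 1.53 times higher in HNRNPD siRNA replicate 3 than in the mean of replicates 1 and 2, at like levels of HNRNPD, leaves both open.

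The fall of glycolysis, NRF2 and ribosomal protein genes covers 114 genes, with a median log2 fold change of -0.594. Removing the trend with gene length and GC content over 14314 coding genes left a median of -0.628 (bootstrap 95% interval -0.762 to -0.49), and that trend took 0.4% of the variance. Relative to coding genes of like expression the median was -0.526 (-0.664 to -0.456). The 53 members whose exons overlap no other gene had a median of -0.672 (-0.879 to -0.504). The bootstrap drew genes, taken as independent, within the same 6 libraries. Its intervals therefore do not measure the spread between libraries, and the estimated correlation reached 0.76 for ribosomal protein genes. In these libraries, the medians argue against the 3 technical trends as the whole cause. Reads shared with copies elsewhere in the genome were not tested and stay open beside a response of the cells to the HNRNPD siRNA.

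Silencing of other mRNAs through siRNA seed matches in their 3' untranslated regions was tested for the genes that fell, since the siRNA sequences are not given in the sources used here. Over 12483 coding genes, 16236 heptamers were screened with length, GC content and expression held constant. The one most strongly associated with lower values, GTCAGCA, had t = -4.49 and does not occur in HNRNPD mRNA. Under the prediction written beforehand this outcome counts against the explanation, as the largest t in the higher direction was also larger in size, at 5.18. The next heptamer, TTTGTTT, does occur in HNRNPD mRNA and had t = -4.29. With a margin of 1 in t, which the prediction did not hold, the rank decides nothing. Heptamers that hold TCAGCA ranked 1, 5, 6, 10 and 15 on the lower side, at t = -4.49 to -3.49. Of these, ATCAGCA and TCAGCAA occur in HNRNPD mRNA. On the higher side, heptamers that hold GGAGAA ranked 1, 2, 3, 6, 7 and 9, at t = 5.18 to 3.75. Such families were not tested as a unit, and their heptamers overlap. No t was adjusted for the 16236 heptamers screened, and the effects were small, at a log2 value of -0.097 for GTCAGCA and 0.087 for AGGAGAA. A seed effect cannot be read from these ranks. No heptamer of HNRNPD mRNA, taken alone, could go with more than 5.6% of the 4426 genes that fell (upper 95% bound). The heptamer with this largest bound occurs in 5623 genes, and for heptamers that frequent, direct silencing behind most of the falls is argued against. Rarer ones, such as ATCAGCA in 1502 genes or ATACCGT in 221, occur in too few genes to hold most of the falls. For these the outcome was set in advance and tests nothing. Falls that follow indirectly from a silenced gene are not covered. This bound covers 1 heptamer at a time and only those read from HNRNPD mRNA itself. A seed with sites in several heptamers, or from the opposite siRNA strand, was not bounded. Seed effects of several heptamers or sequences, or of the control siRNA, may remain, and the largest t in the higher direction was 5.18, for AGGAGAA.

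The hypothesis that the loss of HNRNPD acts through the AU-rich nonamer TTATTTATT in 3' untranslated regions was tested over 1165 genes with it and 10281 without it. Only the longest annotated region of each gene was searched. The values compared were log2 fold changes with extreme values capped and the trends with length, GC content and expression removed. At like length, GC content and expression their medians differed by 0.014 (bootstrap 95% interval over genes -0.018 to 0.055, permutation p = 0.46, two-sided). The sizes of change in either direction differed by -0.012 (-0.044 to 0.026, permutation p = 0.52, two-sided). A common effect larger than these bounds on genes with this nonamer in that annotated region is therefore argued against. Which 3' untranslated regions A549 cells use was not tested, and effects on single mRNAs may exist.

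The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 11490 genes, and 1 of the 10 splits, the real one, gave as many. The highest count of another split was 0 in edgeR, where 95 to 191 genes had an unadjusted p under 0.05. Every other split puts libraries of both siRNAs in each group, so the difference between siRNAs adds to the spread within groups. Few calls were therefore set in advance, and these counts do not tell whether chance gave the calls of the real split.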
